A study of Mus musculus with 33 samples.

How the data were processed

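Livers of mice were collected at 11 times from 0 to 14 days (d) after a 70% partial hepatectomy, with 3 livers per time that the labels call biological replicates. Per the labels' protocols, total RNA was extracted with Trizol and 5 µg was labelled with biotin using a 3' amplification kit and hybridized to Affymetrix mouse genome arrays. The authors summarized the probes with RMA, per the submitters' processing notes (version not given in the sources used here), and the deposited values are on a log2 scale, which the values bear out: each array runs from about 1.68 to 1.85 at its lowest to 14.80 to 14.89 at its highest, and array medians lie between 5.32 and 5.38. RMA subtracts a modelled background, makes the distributions of the arrays alike and combines the probes of a probe set, so a shift common to most genes would be removed and differences near the floor are compressed. A description field of the labels speaks of cells from fat, while the tissue and source fields give liver; the arrays were read as liver, and the levels of albumin and of an adipocyte gene are given with the results.

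The value table holds 45101 probe sets, each column matched to its sample by its name. The platform annotation given with the data paired 34945 probe sets with a single gene symbol and 932 with several, and left 9211 unnamed. The 64 Affymetrix control probe sets are not counted with a single symbol, and those without annotation are among the unnamed. Of the single-symbol probe sets 34754 matched a gene of the reference gene table by Entrez number, and 0 symbols changed. Controls were left out, and a gene was never named from a probe set with several symbols. The probe set with the highest mean over all arrays stood for each of 18193 genes, and genes with a log2 value of 5 or more on at least 3 arrays were tested, which left 13642 and dropped 4551. Probe sets without a single symbol were tested separately by the same fit. No named gene had another probe set called in the opposite direction. Signal near the array floor limits how small a change can be seen, and no count depth exists for arrays.

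A linear model with a mean per time was fitted to all 33 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 22 residual degrees of freedom, prior degrees of freedom 3.69), so that all comparisons share an estimate of the spread. Each of the 10 later times was compared with 0 d, 1.5 d was compared with the mean of 1 d and 2 d, and the moderated F-test over the 10 differences asked which genes varied. P-values are two-sided and adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05, and genes changed at least 2-fold are counted beside. P-values measure the spread between livers within a time. The same 0 d arrays enter all 10 comparisons, so these are not independent of each other. No 2 arrays of a group held identical values.

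Before the data were examined, 38 lists of genes were fixed for regenerating liver, with 760 listed genes of which 650 were measured, and 9 of the lists hold markers of other cell types. For each list and time the members past the threshold were counted over all genes and adjusted over the list alone. The list was also tested with limma's camera at a preset correlation of 0.01, adjusted over the 380 tests, with a correlation estimated from the data, and with fry, which asks whether members move on balance in a direction without comparing them with other genes. The rule for named genes, also fixed then, took per comparison the 5 highest and 5 lowest differences among genes past the threshold whose 3 arrays lay wholly on one side of the 0 d arrays, leaving out clone and model names, and up to 4 members per list past the threshold with the largest differences. Any member of the clock, ligand and receptor and sex chromosome lists could also be named. Genes outside this rule are named as such, and genes shown per array in a plot serve to check the labels.

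The steps were tested on simulated data for the 33 arrays, with 200 of 13642 genes changed at 2 d. Against 0 d, 49.3% of changes of 0.5 on the log2 scale were recovered, 92.5% of changes of 1 and 100% of changes of 2. There were 13 false calls (7.47% of calls), and camera called 0 of 20 unchanged lists. The simulated genes varied independently of each other. The count of 0 thus does not show how camera behaves on lists of correlated genes. The alternatives tried were no filter and a filter at a log2 value of 7, the mean of a gene's probe sets, quantile normalization and a shift to a common median, an intensity trend with a robust prior, array weights, the replicate number as a fixed term, only the arrays compared, a joint adjustment over the 10 comparisons, and each array left out in turn. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.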

Results

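Gene expression was measured in mouse liver before and after a 70% partial hepatectomy, an operation that removes most of the liver and is followed by regrowth of the remnant. Total RNA was hybridized to 33 Affymetrix mouse arrays, with 3 biological replicates at each of 11 times. These were 0 days (d), every 0.25 d up to 1 d, 1.5 d, 2 d, 3 d and 4 d, and lastly 7 d and 14 d after surgery. The 0 d livers were the reference for every comparison, and no sham-operated group is named in the labels, so effects of the operation itself and of tissue loss are measured together. Array medians lay between 5.32 and 5.38 on the log2 scale, and between 12468 and 12905 of the 13642 genes tested reached a log2 value of 5 on an array. Albumin (Alb) lay between 14.60 and 14.80 on all 33 arrays, the Y-linked gene Eif2s3y between 7.59 and 9.50, and Xist, expressed from the inactive X chromosome of females, between 4.73 and 5.30. Precision is limited by the number of arrays, 3 per time.

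The time course asks which genes leave their resting level after loss of liver tissue, and when. Of 13642 genes, 9470 (69.4%) varied over the 11 times by limma's moderated F-test. Among these, the time farthest from 0 d was 0.25 d for 3480 genes (36.7%) and 0.5 d for 1861, while 2 d and 3 d were farthest for 1027 and 903 genes and 14 d for 205. Differences below are log2 differences from the 0 d mean with the standard error of the fit, from 3 arrays per group, and genes are said to rise or fall where the adjusted p was under 0.05. Signals near a log2 value of 5 or below lie close to the floor of the arrays, so a difference that starts or ends there is a lower bound on the size of the change. Lists of genes fixed before the data were examined were also tested with camera, which made 120 calls. With the correlation between genes estimated from the data 0 of these were kept, and the lowest adjusted p was 0.194. Statements on lists therefore rest on the counts of members that passed the test per gene.

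**Figure D1:**
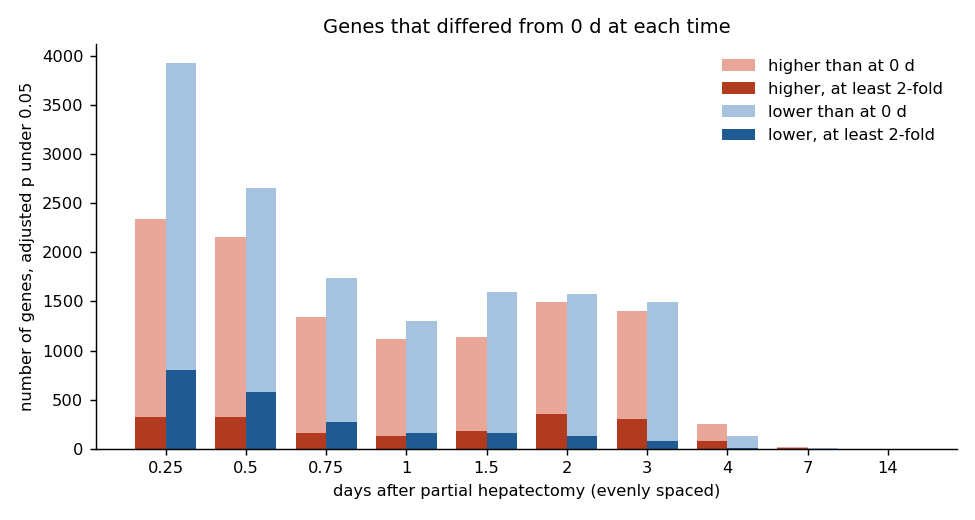
Number of genes higher (red bars) and lower (blue bars, beside them) than at 0 d at each time after 70% partial hepatectomy. Genes changed at least 2-fold are in the darker shade, and times are evenly spaced on the x axis. The number falls from 6265 genes at 0.25 d to 2416 at 1 d, is 3074 at 2 d and 2 at 14 d.

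At 0.25 d, acute phase genes rose and genes of cholesterol and bile acid synthesis fell. Of 25 measured acute phase genes, 22 rose and 0 fell (23 and 0 adjusted over the list alone), led by the iron-siderophore binding protein Lcn2 (7.78 ± 0.88, adjusted p = 1.87e-07, from 0 d values of 4.64 to 6.27), serum amyloid Saa2 (5.39 ± 0.84) and metallothionein Mt2 (4.73 ± 0.82). Camera for acute phase genes at 0.25 d gave adjusted p = 2.31e-13, and adjusted p = 0.276 with an estimated correlation. Immediate early genes, which respond to stimuli without new protein synthesis, rose in 15 of 19 cases (15 adjusted over the list alone), among them Socs3 by 3.69 ± 0.67, Egr1 by 2.58 ± 0.74 and Junb by 2.36 ± 0.38. Camera for immediate early genes at 0.25 d gave adjusted p = 2.42e-06, and adjusted p = 0.276 with an estimated correlation. Of 20 cholesterol synthesis genes 18 fell and 0 rose (18 and 0 adjusted over the list alone), including Insig1 by -3.63 ± 0.41 and Fdps by -2.53 ± 0.35. Camera for cholesterol synthesis genes at 0.25 d gave adjusted p = 8.14e-07, and adjusted p = 0.572 with an estimated correlation. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell to a mean of 4.88 at the floor (-6.45 ± 0.62, adjusted p = 2.17e-08), and 11 of 19 bile acid genes fell (11 adjusted over the list alone). Camera for bile acid genes at 0.25 d gave adjusted p = 0.00758, and adjusted p = 0.499 with an estimated correlation.

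Other lipid genes also moved at 0.25 d. Of 17 lipogenesis genes 10 fell and 1 rose (11 and 1 adjusted over the list alone), with the lipogenic transcription factor Srebf1 at -3.73 ± 0.21 and the citrate lyase Acly at -2.10 ± 0.27. Camera for lipogenesis genes at 0.25 d gave adjusted p = 0.000278, and adjusted p = 0.397 with an estimated correlation. Fatty acid oxidation genes went up in 14 of 19 cases and down in 1 (15 and 1 adjusted over the list alone), with Cyp4a14 at 4.86 ± 0.59 and the pyruvate dehydrogenase kinase Pdk4 at 3.73 ± 0.65. Camera for fatty acid oxidation genes at 0.25 d gave adjusted p = 1.94e-07, and adjusted p = 0.256 with an estimated correlation. Lipid droplet genes rose in 8 of 17 cases and fell in 2 (9 and 3 adjusted over the list alone), with the droplet protein Cidec at 5.31 ± 0.55, Plin2 at 1.81 ± 0.16 and the fatty acid binding protein Fabp4 at 2.06 ± 0.53. Camera for lipid droplet genes at 0.25 d gave adjusted p = 0.00221, and adjusted p = 0.402 with an estimated correlation. Cidec and Fabp4 are also adipocyte markers, and the adipocyte hormone Adipoq was raised on single arrays, at 5.80 on 0.25 d replicate 2 and 5.38 on 0 d replicate 3 against 3.28 and 2.76 on the other 0.25 d arrays and 2.83 and 2.97 on the other 0 d arrays. Of 24 drug metabolism genes 13 fell and 2 rose (15 and 2 adjusted over the list alone), with the aldehyde oxidase Aox3 at -2.31 ± 0.32 and Cyp2b10 at 2.26 ± 0.32. Camera for drug metabolism genes at 0.25 d gave adjusted p = 0.0469, and adjusted p = 0.662 with an estimated correlation. That call was lost without 0 d replicate 1 or 3 or 0.25 d replicate 2 or 3 (adjusted p = 0.0863, 0.168, 0.0794 and 0.0517). Genes known to be higher in male liver fell in 6 of 13 cases and rose in 1 (7 and 1 adjusted over the list alone), with the steroid enzyme Hsd3b5 at -7.39 ± 0.62, ending at a mean of 4.67 at the floor, and Keg1 at -4.60 ± 0.53. Camera for male-biased genes at 0.25 d gave adjusted p = 0.0189, and adjusted p = 0.623 with an estimated correlation.

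Most DNA replication genes were lower than at 0 d at this time. Of 36 DNA replication genes 22 fell and 2 rose at 0.25 d (23 and 3 adjusted over the list alone), with thymidine kinase Tk1 at -2.85 ± 0.28 and the replication factor Mcm10 at -2.72 ± 0.32 (camera adjusted p = 0.000609, and adjusted p = 0.721 with an estimated correlation), while the cyclin-dependent kinase inhibitor Cdkn1a rose by 4.25 ± 0.46 (adjusted p = 9.13e-08). Ribosome biogenesis genes rose in 16 of 32 cases and fell in 1 (16 and 1 adjusted over the list alone), with Nop58 at 1.56 ± 0.25 and Tsr1 at 1.23 ± 0.21. Camera for ribosome biogenesis genes at 0.25 d gave adjusted p = 1.28e-05, and adjusted p = 0.582 with an estimated correlation. Unfolded protein response genes rose in 11 of 22 cases and fell in 1 (14 and 1 adjusted over the list alone), with Creld2 at 2.54 ± 0.41 and Dnajb9 at 1.57 ± 0.26. Camera for unfolded protein response genes at 0.25 d gave adjusted p = 8.58e-05, and adjusted p = 0.582 with an estimated correlation. Neutrophil and monocyte markers rose in 6 of 15 cases and fell in 0 (6 and 0 adjusted over the list alone), with the calgranulins S100a9 at 2.56 ± 0.56 and S100a8 at 2.53 ± 0.69. Camera for neutrophil and monocyte genes at 0.25 d gave adjusted p = 0.00266, and adjusted p = 0.448 with an estimated correlation. The list of growth factor ligands and receptors also holds binding proteins. Of its 24 genes 13 rose and 3 fell (13 and 3 adjusted over the list alone), with the binding protein Igfbp1 at 3.50 ± 0.69, the oncostatin M receptor Osmr at 2.17 ± 0.34 and the leukemia inhibitory factor receptor Lifr at -2.19 ± 0.16. Camera for ligand and receptor genes at 0.25 d gave adjusted p = 0.0327, and adjusted p = 0.194 with an estimated correlation. It was 0.0521 without 0 d replicate 2. Over all genes, 6265 of 13642 (45.9%) passed at 0.25 d, 2340 higher and 3925 lower, of which 322 and 799 by at least 2-fold. With quantile normalization of the arrays the split was 3075 higher and 3150 lower, and with only the 6 arrays compared in the fit 3702 genes passed. Replicate 1 of 0.25 d had the highest 18S signal of all arrays, 12.99, and correlated with its group at 0.973.

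At 0.5 d acute phase and unfolded protein response genes were higher than at 0 d, and interferon response genes lower. The acute phase list had 21 of 25 genes up and 0 down (22 and 0 adjusted over the list alone; camera adjusted p = 1.58e-13, and adjusted p = 0.276 with an estimated correlation), with Lcn2 at 7.89 ± 0.88, Saa2 at 5.53 ± 0.84 and Saa1 at 3.88 ± 0.50. Unfolded protein response genes rose in 18 of 22 cases and fell in 0 (18 and 0 adjusted over the list alone), with Creld2 at 3.57 ± 0.41 and the chaperone cofactors Sdf2l1 at 2.88 ± 0.36 and Manf at 2.08 ± 0.27. Camera for unfolded protein response genes at 0.5 d gave adjusted p = 1.54e-12, and adjusted p = 0.194 with an estimated correlation. Ribosome biogenesis genes rose in 22 of 32 cases and fell in 1 (24 and 1 adjusted over the list alone). Camera for ribosome biogenesis genes at 0.5 d gave adjusted p = 2.78e-07, and adjusted p = 0.477 with an estimated correlation. Interferon response genes fell in 13 of 19 cases and rose in 0 (14 and 0 adjusted over the list alone), with the chemokine Cxcl9 at -2.38 ± 0.38 and Ifit3 at -2.17 ± 0.45. Camera for interferon response genes at 0.5 d gave adjusted p = 2.44e-05, and adjusted p = 0.661 with an estimated correlation. Some markers of Kupffer cells were lower at the same time: of 15 markers 4 fell, among them Csf1r (-1.26 ± 0.24), Clec4f (-1.20 ± 0.23) and Timd4 (-1.12 ± 0.32), and Marco (1.92 ± 0.63) rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.179, and adjusted p = 0.902 with an estimated correlation).

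At 0.5 d drug metabolism, lipogenesis, bile acid and male-biased genes fell, while fatty acid oxidation genes rose. Of 19 fatty acid oxidation genes 11 rose and 2 fell (11 and 2 adjusted over the list alone), with Cyp4a14 at 4.64 ± 0.59 and the lipid-sensing receptor Ppara at -1.19 ± 0.26. Camera for fatty acid oxidation genes at 0.5 d gave adjusted p = 0.0131, and adjusted p = 0.666 with an estimated correlation. Drug metabolism genes fell in 17 of 24 cases and rose in 1 (17 and 1 adjusted over the list alone), with Cyp1a2 at -2.96 ± 0.34 and the glucuronosyltransferase Ugt2b1 at -2.44 ± 0.20. Camera for drug metabolism genes at 0.5 d gave adjusted p = 1.40e-07, and adjusted p = 0.194 with an estimated correlation. Lipogenesis genes fell in 14 of 17 cases and rose in 0 (15 and 0 adjusted over the list alone), with Thrsp at -4.88 ± 0.59, Srebf1 at -3.25 ± 0.21 and the desaturase Scd1 at -2.53 ± 0.46. Camera for lipogenesis genes at 0.5 d gave adjusted p = 1.48e-07, and adjusted p = 0.194 with an estimated correlation. Bile acid genes fell in 12 of 19 cases and rose in 0 (13 and 0 adjusted over the list alone), with Cyp7a1 at -6.39 ± 0.62, again at the floor, and the bile salt export pump Abcb11 at -1.70 ± 0.39. Camera for bile acid genes at 0.5 d gave adjusted p = 1.74e-06, and adjusted p = 0.194 with an estimated correlation. Male-biased genes fell in 9 of 13 cases and rose in 0 (9 and 0 adjusted over the list alone), with Hsd3b5 at -6.05 ± 0.62 and Ugt2b38 at -3.72 ± 0.46. Camera for male-biased genes at 0.5 d gave adjusted p = 5.39e-06, and adjusted p = 0.215 with an estimated correlation. The uridine phosphorylase Upp2 was at -7.40 ± 0.41 (adjusted p = 1.16e-12), with a mean of 4.30 near the floor of the arrays, and the apolipoprotein Apoa4 rose by 4.21 ± 0.38. The counts at 0.5 d were 4808 genes (35.2%), 2158 higher and 2650 lower, of which 321 and 575 by at least 2-fold. With only the 6 arrays compared in the fit 2443 genes passed, and 0.5 d replicate 3 had the lowest correlation with its own group of all arrays, 0.970.

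At 0.75 d lipogenesis genes were low and acute phase and unfolded protein response genes high. The desaturase Scd1 (-4.43 ± 0.46), Thrsp (-4.23 ± 0.59) and the pyruvate kinase Pklr (-1.47 ± 0.26) were among 14 of 17 lipogenesis genes that fell, while 0 rose (15 and 0 adjusted over the list alone). Camera for lipogenesis genes at 0.75 d gave adjusted p = 2.34e-10, and adjusted p = 0.194 with an estimated correlation. Orm2 (4.36 ± 0.77) and Saa2 (5.63 ± 0.84) were among 20 of 25 acute phase genes that rose, while 0 fell (22 and 0 adjusted over the list alone). Camera for acute phase genes at 0.75 d gave adjusted p = 1.01e-17, and adjusted p = 0.194 with an estimated correlation. Sdf2l1 (2.70 ± 0.36) and the chaperone Hyou1 (1.48 ± 0.18) were among 16 of 22 unfolded protein response genes that rose, while 0 fell (16 and 0 adjusted over the list alone). Camera for unfolded protein response genes at 0.75 d gave adjusted p = 6.42e-12, and adjusted p = 0.208 with an estimated correlation. The carboxylesterase Ces1d (-2.72 ± 0.45) and Ugt2b1 (-2.38 ± 0.20) were among 15 of 24 drug metabolism genes that fell, while 1 rose (18 and 1 adjusted over the list alone). Camera for drug metabolism genes at 0.75 d gave adjusted p = 6.07e-09, and adjusted p = 0.194 with an estimated correlation. Male-biased genes fell in 10 of 13 cases (10 adjusted over the list alone; camera adjusted p = 9.76e-07, and adjusted p = 0.194 with an estimated correlation), and Cyp7a1 was at -5.17 ± 0.62 (adjusted p = 9.11e-07). Of 20 cholesterol synthesis genes 2 rose and 2 fell (2 and 2 adjusted over the list alone), with the squalene epoxidase Sqle at 1.61 ± 0.48 and Tm7sf2 at -1.38 ± 0.16. At 0.75 d 3076 genes (22.5%) passed, 1342 higher and 1734 lower, of which 157 and 271 by at least 2-fold. With quantile normalization the split turned to 1590 higher and 1492 lower.

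At 1 d acute phase genes remained up, and more DNA replication genes rose than fell. Lcn2 (7.76 ± 0.88), Orm2 (4.70 ± 0.77) and Saa1 (3.92 ± 0.50) were among 19 of 25 acute phase genes that rose, while 0 fell (20 and 0 adjusted over the list alone). Camera for acute phase genes at 1 d gave adjusted p = 6.16e-19, and adjusted p = 0.194 with an estimated correlation. Cdc6 (1.34 ± 0.39, adjusted p = 0.0176), which loads the replicative helicase, and the helicase subunits Mcm5 (1.24 ± 0.39) and Mcm6 (1.24 ± 0.36) were among 7 of 36 DNA replication genes that rose, while 2 fell, Tk1 among them at -1.80 ± 0.28 (11 and 2 adjusted over the list alone). Camera for DNA replication genes at 1 d gave adjusted p = 0.0186, and adjusted p = 0.834 with an estimated correlation. The call was lost without 0 d replicate 1 or 1 d replicate 2 or 3 (adjusted p = 0.0513, 0.0727 and 0.121). Cholesterol synthesis genes rose in 7 of 20 cases and fell in 1 (9 and 1 adjusted over the list alone), with Sqle at 1.62 ± 0.48 and Cyp51 at 1.36 ± 0.35. Camera for cholesterol synthesis genes at 1 d gave adjusted p = 0.0166, and adjusted p = 0.834 with an estimated correlation. Without 0 d replicate 1 it was lost (adjusted p = 0.0822). Heat shock genes rose in 7 of 14 cases and fell in 0 (7 and 0 adjusted over the list alone), with Hsp90aa1 at 1.00 ± 0.22 and Hsph1 at 0.98 ± 0.33. Camera for heat shock genes at 1 d gave adjusted p = 8.58e-05, and adjusted p = 0.400 with an estimated correlation. Their median difference went from 0.390 to 0.254 without 1 d replicate 1 (camera adjusted p = 0.00582). Upp2 (-4.33 ± 0.41), the methyltransferase Inmt (-3.89 ± 0.52) and the neprilysin gene Mme (-3.34 ± 0.44) were among the largest decreases. At 1 d 2416 genes (17.7%) passed, 1113 higher and 1303 lower, of which 132 and 157 by at least 2-fold, and 1581 passed without 1 d replicate 1.

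Genes of the circadian clock differed from 0 d at several times. At 1 d 8 of 18 clock genes fell and 2 rose (10 and 4 adjusted over the list alone; camera adjusted p = 0.0575), with the output factor Dbp at -3.51 ± 0.86 (adjusted p = 0.00527), Per3 at -2.10 ± 0.49 and Arntl, whose protein is BMAL1, at 1.95 ± 0.51. At 1.5 d 10 of 18 fell and 1 rose (10 and 2 adjusted over the list alone), with Dbp at -2.82 ± 0.86 and Usp2 at -1.80 ± 0.55 (camera adjusted p = 0.0242, and adjusted p = 0.519 with an estimated correlation). These differences rest on a spread within 0 d: Dbp was 11.05 and 11.65 on 0 d replicates 1 and 2 and 8.36 on replicate 3, and Arntl 5.28, 5.39 and 8.12. At 14 d Dbp was 8.34 on replicate 1 and 11.36 and 10.93 on the others. At 7 d it was 10.23 on replicate 3 and 11.45 and 11.35 on the others.

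At 1.5 d DNA replication genes rose broadly. The licensing factor Cdc6 (3.08 ± 0.39), Mcm5 (2.98 ± 0.39) and the methylation maintenance factor Uhrf1 (2.88 ± 0.35) were among 29 of 36 DNA replication genes that rose, while 1 fell (31 and 1 adjusted over the list alone). Camera for DNA replication genes at 1.5 d gave adjusted p = 2.20e-20, and adjusted p = 0.194 with an estimated correlation. Cyclins Ccne2 (1.78 ± 0.39) and Ccnd1 (1.55 ± 0.44) were among 9 of 18 G1/S regulators that rose, while 0 fell (11 and 0 adjusted over the list alone). Camera for G1/S genes at 1.5 d gave adjusted p = 1.93e-07, and adjusted p = 0.194 with an estimated correlation. Top2a (1.82 ± 0.37) and Mki67 (1.77 ± 0.49), the gene of the Ki-67 proliferation antigen, were among 21 of 39 mitosis genes that rose, while 0 fell (22 and 0 adjusted over the list alone). Camera for mitosis genes at 1.5 d gave adjusted p = 9.72e-10, and adjusted p = 0.645 with an estimated correlation. Immediate early genes rose in 3 of 19 cases and fell in 1 (5 and 1 adjusted over the list alone), with Egr1 at 3.20 ± 0.74, Fos at 2.52 ± 0.88 and the phosphatase gene Dusp1 at -1.10 ± 0.33. Camera for immediate early genes at 1.5 d gave adjusted p = 0.0164, and adjusted p = 0.666 with an estimated correlation. Without 0 d replicate 1 that call was lost (adjusted p = 0.109), and the median difference of 0.593 went to 0.336 without 1.5 d replicate 2 and 0.309 without replicate 3. Acute phase genes rose in 17 of 25 cases and fell in 1 (17 and 1 adjusted over the list alone; camera adjusted p = 5.17e-14, and adjusted p = 0.270 with an estimated correlation), and Afp, the fetal alpha-fetoprotein gene, rose by 1.16 ± 0.17. The hepcidin gene Hamp2 (-3.61 ± 0.40) and the male-biased Ugt2b38 (-3.32 ± 0.46) fell. At 1.5 d 2729 genes (20%) passed, 1137 higher and 1592 lower, of which 178 and 158 by at least 2-fold.

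The 1.5 d samples, with 0.25, 0.5 and 0.75 d, carry later sample numbers than the other times, and lie 0.5 d from both 1 d and 2 d. The hours of surgery and collection are not in the labels. For this reason 1.5 d was also set against the mean of 1 d and 2 d. The contrast called 3 genes by limma, with 975 at an unadjusted p under 0.05. They were Lifr (0.95 ± 0.14, adjusted p = 0.00593), Mllt11 (-0.63 ± 0.10, adjusted p = 0.00942) and Tbcb (-0.38 ± 0.07, adjusted p = 0.0436), Mllt11 and Tbcb being named after their values were seen. The count was 0 without 1.5 d replicate 1 or replicate 2, 42 without 2 d replicate 2, and 0 with the mean of a gene's probe sets or with only the 9 arrays compared, and 292 with array weights.

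At 2 d G1/S regulators, DNA replication genes and mitosis genes were high. Mcm5 (3.93 ± 0.39, adjusted p = 7.67e-08), Uhrf1 (3.85 ± 0.35) and Cdc6 (3.79 ± 0.39) were among 32 of 36 DNA replication genes that rose, while 1 fell (32 and 1 adjusted over the list alone). Camera for DNA replication genes at 2 d gave adjusted p = 3.73e-37, and adjusted p = 0.194 with an estimated correlation. Ect2 (3.72 ± 0.36), needed for cytokinesis, and Mki67 (3.70 ± 0.49, adjusted p = 4.40e-06) were among 37 of 39 mitosis genes that rose, while 0 fell (38 and 0 adjusted over the list alone). Camera for mitosis genes at 2 d gave adjusted p = 2.94e-32, and adjusted p = 0.211 with an estimated correlation. The mean of the mitosis list was 6.02 on 2 d replicate 2 and at least 7.98 on replicates 1 and 3, and 5.28 over the 0 d arrays. Ccnd1 (2.37 ± 0.44) and E2f8 (2.00 ± 0.35) were among 14 of 18 G1/S regulators that rose, while 0 fell (14 and 0 adjusted over the list alone). Camera for G1/S genes at 2 d gave adjusted p = 3.65e-13, and adjusted p = 0.194 with an estimated correlation. The cohesin acetyltransferase Esco2 rose by 4.59 ± 0.41 and the neutrophil protease Prtn3 by 4.37 ± 0.65. Targets of p53 rose in 8 of 15 cases and fell in 0 (8 and 0 adjusted over the list alone), with Cdkn1a at 1.86 ± 0.46 and Eda2r at 1.44 ± 0.28. Camera for p53 target genes at 2 d gave adjusted p = 0.00274, and adjusted p = 0.233 with an estimated correlation.

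Cholesterol synthesis genes rose in 8 of 20 cases at 2 d and fell in 1 (13 and 1 adjusted over the list alone), with Sqle at 1.61 ± 0.48, Hmgcs1 at 1.57 ± 0.45 and Lss at 1.21 ± 0.32. Camera for cholesterol synthesis genes at 2 d gave adjusted p = 0.000135, and adjusted p = 0.666 with an estimated correlation. Bile acid genes fell in 7 of 19 cases and rose in 0 (8 and 0 adjusted over the list alone), with the sterol hydroxylase Cyp8b1 at -2.85 ± 0.66. Camera for bile acid genes at 2 d gave adjusted p = 0.000457, and adjusted p = 0.287 with an estimated correlation. The major histocompatibility class II gene H2-Aa was at -3.30 ± 0.34 (adjusted p = 1.55e-07). Acute phase genes were up in 17 of 25 cases and down in 0 at 2 d (19 and 0 adjusted over the list alone; camera adjusted p = 3.62e-12, and adjusted p = 0.307 with an estimated correlation). At 2 d 3074 genes (22.5%) passed, 1494 higher and 1580 lower, of which 353 and 131 by at least 2-fold, and 1663 passed with only the 6 arrays compared in the fit. The split turned to 842 higher and 821 lower in that fit, and to 1492 and 1489 with each array shifted to a common median.

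**Figure D2:**
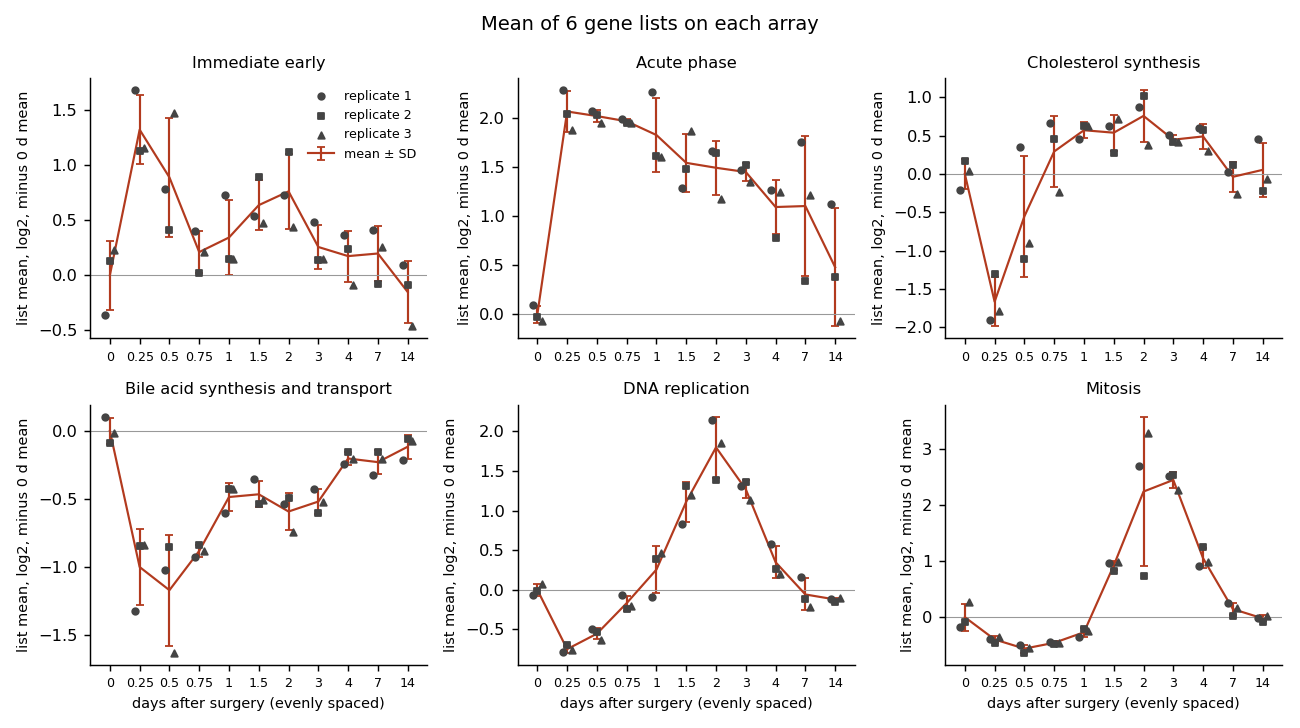
Mean log2 value of 6 lists of genes on each array minus their mean at 0 d, against time after surgery in days (evenly spaced), with points marked by replicate and lines for the group mean ± SD of 3 arrays. Acute phase arrays of 0.25 to 3 d lie above those of 0 d, and in the mitosis panel 2 d replicate 2 lies below the other 2 d arrays.

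At 3 d mitosis genes were high and DNA replication genes were still raised. Cyclin Ccnb2 (4.21 ± 0.62), Mki67 (4.04 ± 0.49) and the survivin gene Birc5 (3.85 ± 0.42) were among 36 of 39 mitosis genes that rose, while 0 fell (38 and 0 adjusted over the list alone). Camera for mitosis genes at 3 d gave adjusted p = 3.73e-37, and adjusted p = 0.194 with an estimated correlation. Mcm5 (2.95 ± 0.39) and the ribonucleotide reductase subunit Rrm2 (2.80 ± 0.48) were among 30 of 36 DNA replication genes that rose, while 0 fell (30 and 1 adjusted over the list alone). Camera for DNA replication genes at 3 d gave adjusted p = 1.75e-24, and adjusted p = 0.194 with an estimated correlation. Eda2r (1.86 ± 0.28) and Cdkn1a (1.57 ± 0.46) were among 8 of 15 p53 targets that rose, while 0 fell (8 and 0 adjusted over the list alone). Camera for p53 target genes at 3 d gave adjusted p = 0.000609, and adjusted p = 0.194 with an estimated correlation. The scavenger receptor Marco (3.33 ± 0.63) and Cd5l (1.38 ± 0.37) were among 5 of 15 Kupffer cell markers that rose, while 0 fell (6 and 0 adjusted over the list alone). Camera for Kupffer cell genes at 3 d gave adjusted p = 0.000227, and adjusted p = 0.666 with an estimated correlation. Male-biased genes fell in 8 of 13 cases and rose in 0 (9 and 0 adjusted over the list alone), with Hsd3b5 at -3.00 ± 0.62 and the hydroxylase Cyp4a12a at -2.71 ± 0.29. Camera for male-biased genes at 3 d gave adjusted p = 3.99e-06, and adjusted p = 0.211 with an estimated correlation. Targets of the antioxidant factor NRF2 rose in 9 of 20 cases and fell in 0 (9 and 0 adjusted over the list alone), with Gstm3 at 2.08 ± 0.54 and Nqo1 at 0.87 ± 0.25. Camera for NRF2 target genes at 3 d gave adjusted p = 0.000671, and adjusted p = 0.458 with an estimated correlation. Their median difference went from 0.311 to 0.466 without 0 d replicate 3. Acute phase genes were up in 17 of 25 cases and down in 0 at 3 d (17 and 0 adjusted over the list alone), with Lcn2 at 6.68 ± 0.88 (camera adjusted p = 7.21e-11, and adjusted p = 0.384 with an estimated correlation). At 3 d 2888 genes (21.2%) passed, 1398 higher and 1490 lower, of which 305 and 82 by at least 2-fold, and 1893 passed without 3 d replicate 2. With only the 6 arrays compared in the fit the split turned to 1369 higher and 1271 lower.

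At 4 d fewer genes differed from 0 d, and acute phase, mitosis and Kupffer cell genes were among the higher ones. Lcn2 (5.15 ± 0.88, adjusted p = 0.00218) and Saa2 (3.91 ± 0.84) were among 10 of 25 acute phase genes that rose, while 0 fell (13 and 0 adjusted over the list alone). Camera for acute phase genes at 4 d gave adjusted p = 7.43e-13, and adjusted p = 0.287 with an estimated correlation. Ccnb2 (2.30 ± 0.62, adjusted p = 0.0419), Mki67 (2.11 ± 0.49) and Top2a (1.63 ± 0.37) were among 8 of 39 mitosis genes that rose, while 0 fell (31 and 0 adjusted over the list alone). Camera for mitosis genes at 4 d gave adjusted p = 6.56e-19, and adjusted p = 0.409 with an estimated correlation. Marco (3.26 ± 0.63) and Cd5l (1.38 ± 0.37) were the 2 of 15 Kupffer cell markers that rose, while 0 fell (11 and 0 adjusted over the list alone). Camera for Kupffer cell genes at 4 d gave adjusted p = 1.30e-09, and adjusted p = 0.409 with an estimated correlation. Of 22 stellate cell and fibroblast markers the collagen Col5a2 (1.11 ± 0.27) and the matrix protein Sparc (1.09 ± 0.19) rose and Ecm1 (-0.75 ± 0.14) fell (4 and 1 adjusted over the list alone). Camera for stellate cell genes at 4 d gave adjusted p = 0.000564, and adjusted p = 0.622 with an estimated correlation. The median difference of that list was 0.382, 0.206 without 0 d replicate 1, where the call was lost (adjusted p = 0.0559), and 0.607 without 0 d replicate 3. The lipoprotein lipase Lpl rose by 1.99 ± 0.33 and the imprinted gene Mest by 1.06 ± 0.18. At 4 d 390 genes (2.86%) passed, 257 higher and 133 lower, of which 77 and 10 by at least 2-fold, with 2277 at an unadjusted p under 0.05. The count was 87 without 0 d replicate 1, 247 without 0 d replicate 2, 138 without 4 d replicate 1 and 161 without 4 d replicate 2, 160 with only the 6 arrays compared in the fit, 954 with a joint adjustment over the 10 comparisons, and 659 without 0.25 d replicate 1 and 0.5 d replicate 3.

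At 7 d 25 genes passed, 17 higher and 8 lower. Lcn2 (4.73 ± 0.88, adjusted p = 0.0238), Saa1 (2.58 ± 0.50), the hepatokine Fgl1 (1.64 ± 0.24, adjusted p = 0.00377) and Itih4 (0.53 ± 0.10) were the 4 of 25 acute phase genes that rose, while 0 fell (16 and 0 adjusted over the list alone). Camera for acute phase genes at 7 d gave adjusted p = 3.93e-20, and adjusted p = 0.194 with an estimated correlation. Marco (3.25 ± 0.63, adjusted p = 0.0256) was the 1 of 15 Kupffer cell markers that rose, while 0 fell (14 and 0 adjusted over the list alone). Camera for Kupffer cell genes at 7 d gave adjusted p = 9.13e-18, and adjusted p = 0.194 with an estimated correlation. Without 7 d replicate 1, whose list mean was 9.75 against 8.54 and 8.59 on replicates 2 and 3 and 7.47 to 8.07 at 0 d, the median difference went from 1.01 to 0.582 (camera adjusted p = 2.2e-09). Sparc (1.12 ± 0.19) was the 1 of 22 stellate cell and fibroblast markers that rose (4 higher and 1 lower adjusted over the list alone). Camera for stellate cell genes at 7 d gave adjusted p = 3.24e-05, and adjusted p = 0.519 with an estimated correlation. The median difference of that list went from 0.327 to 0.197 without 0 d replicate 1 and to 0.211 without 7 d replicate 1 (camera adjusted p = 0.0206 and 0.000629). Neutrophil and monocyte markers passed over all genes in 0 of 15 cases and were higher in 4 adjusted over the list alone. Camera for neutrophil and monocyte genes at 7 d gave adjusted p = 5.54e-06, and adjusted p = 0.194 with an estimated correlation. The list mean was 6.28 on replicate 1 and 5.59 and 5.63 on replicates 2 and 3, against 5.29 to 5.42 at 0 d, and without replicate 1 the camera adjusted p was 0.00404. Wfdc17 rose by 1.61 ± 0.33, and Calr3 (-0.90 ± 0.19) and Bbs10 (-0.74 ± 0.14) fell. The basement membrane collagens Col4a1 (1.05 ± 0.22) and Col4a2 (0.83 ± 0.13), named after their values were seen, were also higher. Lcn2 was 12.24 on 7 d replicate 1, 7.84 on replicate 2 and 10.86 on replicate 3, against 4.64 to 6.27 at 0 d. At 7 d 8 genes were higher by at least 2-fold, and 1761 had an unadjusted p under 0.05.

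The count at 7 d depended on single arrays and on the scaling. It was 0 by limma without 0 d replicate 1 or 7 d replicate 1, 48 without 0 d replicate 2, 38 without 7 d replicate 2 and 4 without 7 d replicate 3, and 0 with only the 6 arrays compared. The split of 17 higher and 8 lower was 14 and 2 with quantile normalization 14 and 12 with each array shifted to a common median, and turned to 21 and 27 without 0 d replicate 2.

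At 14 d 2 genes passed, the chemokine-binding receptor Ackr1 (0.69 ± 0.12) and the phosphoinositide kinase subunit Pik3cd (0.59 ± 0.10), both higher at adjusted p = 0.0448, with 1870 genes at an unadjusted p under 0.05. Mki67, Mcm5, Cyp7a1 and Hsd3b5, among the most changed at earlier times, did not pass at 14 d. Kupffer cell markers passed over all genes in 0 of 15 cases and were higher in 7 adjusted over the list alone. Camera for Kupffer cell genes at 14 d gave adjusted p = 7.28e-10, and adjusted p = 0.400 with an estimated correlation. The list mean was 9.407 on 14 d replicate 1, 8.423 on replicate 2 and 7.995, within the 0 d range of 7.474 to 8.073, on replicate 3. Without replicate 1 the median difference went from 0.699 to 0.341 (camera adjusted p = 0.0151). Lcn2 was 10.84 on 14 d replicate 1 against 6.96 and 5.75 on replicates 2 and 3, and its difference from 0 d was 2.27 ± 0.88 (adjusted p = 0.264). Acute phase genes passed in 0 of 25 cases, also adjusted over the list alone (camera adjusted p = 3.39e-06, and adjusted p = 0.610 with an estimated correlation), with 0 d arrays between 10.76 and 10.92 in list mean and 14 d replicate 1 at 11.95. Without that replicate the camera call was lost (adjusted p = 0.292). The count of genes at 14 d was 0 by limma without 0 d replicate 1 or 3 or without 14 d replicate 1 or 2, 23 without 0 d replicate 2 and 1 without 14 d replicate 3, and its split was 2 higher and 5 lower with each array shifted to a common median and 3 higher and 9 lower with array weights.

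**Figure D3:**
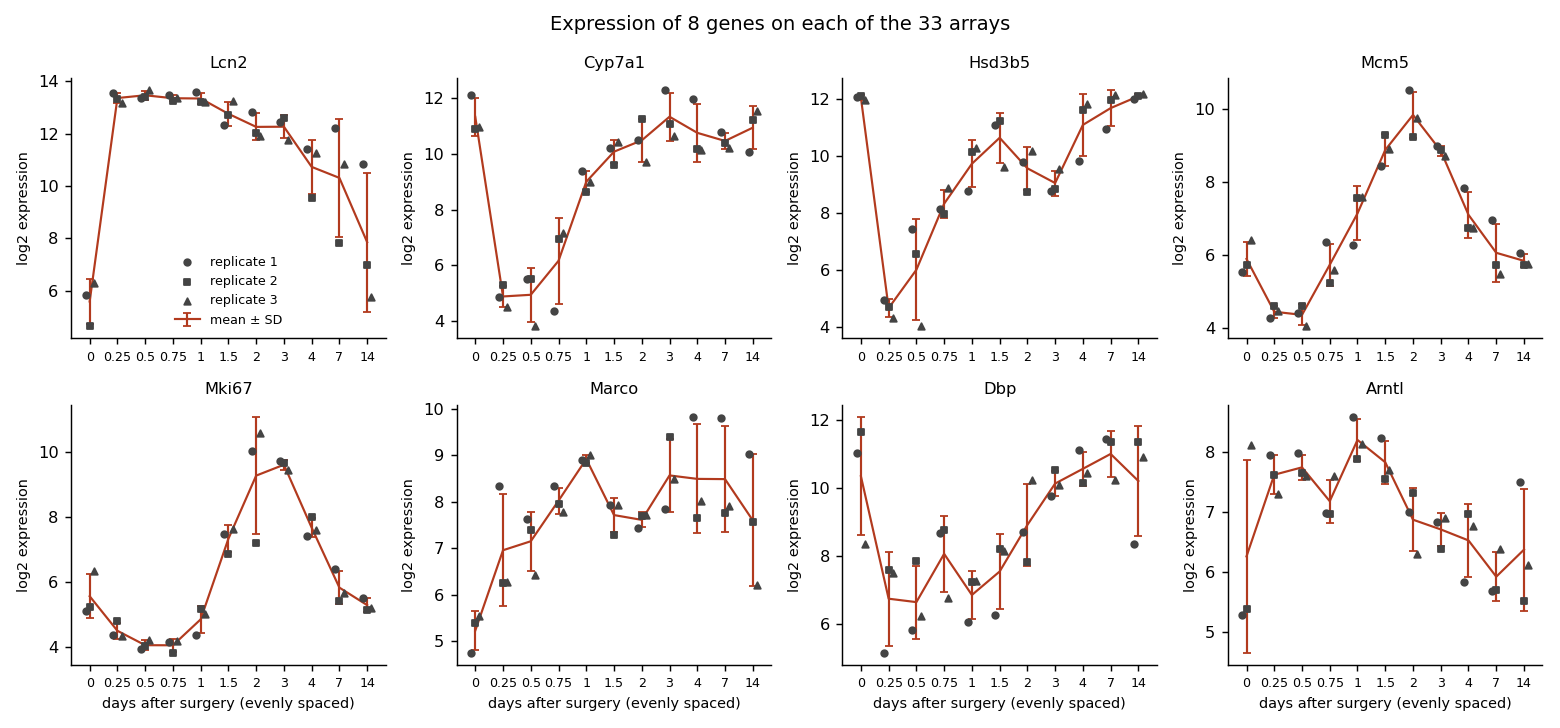
Log2 value of 8 genes on each of the 33 arrays against time after surgery in days (evenly spaced), with points marked by replicate. Lcn2 at 7 d and 14 d spreads from 12.24 to 5.75, Mki67 on 2 d replicate 2 is 7.21 against 10.03 and 10.57, and Dbp on 0 d replicate 3 is 8.36 against 11.05 and 11.65.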

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

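The tests of the clock genes and of the labels of 0 d replicate 3 and 14 d replicate 1, and that of a swap of 2 d replicate 2, were chosen only after the results were seen.

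Camera called some lists lower than at 0 d at a time and higher at another. With an estimated correlation 0 of these calls were kept. The pairs of times below were chosen for this as the farthest apart, so their differences describe the size of the swing and are no further test of it. The median difference of DNA replication genes was 2.45 between 2 d and 0.25 d, and that of mitosis genes 3.15 between 3 d and 0.5 d. For cholesterol synthesis genes it was 2.85 between 2 d and 0.25 d, and for sinusoidal endothelium markers 0.481 between 4 d and 0.75 d, each higher at the later time. With an array left out the calls of mitosis genes at 0.5 d (adjusted p = 0.164 without 0 d replicate 3, 0.0895 without 0.5 d replicate 2) and of sinusoidal endothelium markers at 0.75 d (0.0549, 0.256 and 0.0595 without 0 d replicate 1 or 3 or 0.75 d replicate 3) and 4 d (0.226 and 0.164 without 0 d replicate 2 or 4 d replicate 3) were lost. Of 4290 probe sets without a single gene symbol, which enter no comparison above, 1951 (45.5%) varied over the 11 times, and 1254 of the 4290 differed from 0 d at 0.25 d.

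The clock genes of 0 d replicate 3 and 14 d replicate 1 stood apart from the other arrays of their groups. Other groups also varied. The clock list mean was 7.263 on 7 d replicate 3 against 7.819 and 7.826 on the other 7 d arrays. On 0 d replicate 3 it was 7.569 against 7.932 and 7.894, and on 14 d replicate 1 7.192 against 7.877 and 7.869. The deviations of 0 d replicate 3 and 14 d replicate 1 correlated across 18 clock genes with r = 0.919. Both arrays were picked for these genes, so this restates the pattern and another time of day at collection stays open. An array of 0.25 to 3 d under the 0 d label is argued against by the acute phase mean of 0 d replicate 3, 10.76, below the lowest of the 21 arrays of those times, 12, by more than the 0 d range of 0.164. For 14 d replicate 1 the acute phase mean, 11.95, left such an array open, and the male-biased mean, chosen after that, argues against it at 11.67, above the highest of those arrays, 10.89, by more than the largest SD within a time, 0.444. An array of 4 d under the 14 d label is argued against by the mitosis mean of 14 d replicate 1, 5.266. It lay below the lowest 4 d array, 6.199, by more than the 4 d range of 0.338. That mean left an array of 7 d open, as the lowest 7 d mean was 5.304. The clock genes read per array, a part of the 18, were also set against the 7 d arrays. For each of them 14 d replicate 1 lay outside the 7 d range. Dbp was 8.335 on it against 10.229 to 11.452 at 7 d, and Arntl 7.498 against 5.677 to 6.392. Nfil3 came closest, at 7.932 against 7.276 to 7.86. The near ends of the 7 d ranges of Dbp and Arntl came from 7 d replicate 3. As 14 d replicate 1 was picked for its clock genes, they are no test of its label. An array of 7 d under the 14 d label thus stays open, also one from a liver collected at another time of day.

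The changes at 0.25, 0.5 and 0.75 d fall on samples with later sample numbers, which they share with 1.5 d, so a batch might lie behind them. The 18S probe sets had a median of 11.91 on the arrays with later numbers (10.83 to 12.99) and 11.23 on the others (9.593 to 12.36). Medians of the hybridization controls (10.36 and 10.34) and poly-A spikes (6.142 and 6.166) were close. A batch effect shared with 1.5 d would move 1.5 d away from the mean of 1 d and 2 d in the same direction. For genes called at 0.25, 0.5 and 0.75 d that shift, signed by the early change, had medians of 0.0371, 0.00379 and 0.00293, against median changes of 0.522, 0.555 and 0.509, and its upper quartiles of 0.115, 0.0891 and 0.0881 lay below the lower quartiles of the change, 0.365, 0.381 and 0.363. This argues against such a batch as the cause of most of these changes. The planned reading of the 0.5 d value was also against a time of day shared by 0.5 d and 1.5 d. That reading needs 1.5 d to differ in hour from 1 d and 2 d, and the labels give no hours. Dbp at 1.5 d, 6.255 to 8.203, overlapped 1 d (6.03 to 7.268) and 2 d (7.812 to 10.227). No conclusion on time of day is therefore drawn from it. Effects of time of day, a batch that holds 0.25, 0.5 and 0.75 d but not 1.5 d, and effects of surgery other than tissue loss stay open.

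Mitosis genes on 2 d replicate 2 had a mean of 6.02, while replicates 1 and 3 were at 7.98 or above. A swap with a 1.5 d array is argued against, since the highest 1.5 d mean was 6.258 and no 1.5 d array stood as high as the other 2 d arrays. A weaker signal of every changed gene is argued against as well: the replicate showed 1.17 of the acute phase change of the other replicates and 0.248 of their mitosis change, a ratio of 4.71. Its position was also read over 386 genes outside the cell cycle lists, picked for differing between 1.5 d and 2 d replicates 1 and 3. The median position of replicate 2 was 0.15 between 1.5 d (0) and the other 2 d arrays (1), with quartiles of -0.0385 and 0.392. Picking genes without replicate 2 by itself draws its position toward 0, by an amount that was not measured. Other lists were mixed. The means of replicate 2 for G1/S, acute phase and bile acid genes, 7.601, 12.47 and 10.8, lay within the range of the 1.5 d arrays. Its DNA replication mean, 8.15, lay above their highest, 8.08, and its mitosis mean, 6.019, below their lowest, 6.104. Its male-biased mean, 10.32, lay below their lowest, 10.49. Its means of p53 targets, 7.853, and lipogenesis genes, 10.68, lay above their highest, 7.626 and 10.19. An array of 1.5 d under the 2 d label, or a liver that had reached only that stage by 2 d, may explain the low mitosis mean, and the data do not separate them.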

How the results depend on the processing

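Of the alternatives, leaving out 0.25 d replicate 1 with 0.5 d replicate 3 (the arrays farthest on the first principal component), leaving out 0 d replicate 3 with 14 d replicate 1 (clock genes), and fitting only the earlier sample numbers were chosen after seeing the data. Counts of genes from 0.25 to 3 d stayed within 1.5 times the reported ones except where given here. The causes of the moves were not tested, and smaller fits also hold fewer arrays. With only the groups compared in the fit the counts were 3702 at 0.25 d, 2443 at 0.5 d, 1663 at 2 d, 160 at 4 d, 0 at 7 d, 0 at 14 d and 0 for 1.5 d against 1 d and 2 d. A joint adjustment over the 10 comparisons gave 954 at 4 d, 567 at 7 d and 537 at 14 d, since the many changed genes of the early times loosen it. Without the arrays farthest on the first component 659, 78 and 31 genes passed at 4, 7 and 14 d. Without 0 d replicate 3 and 14 d replicate 1, counts of 48 and 0 were left at 7 and 14 d, and with only the earlier sample numbers 9 and 0. Array weights gave 12 at 7 d, 12 at 14 d and 292 for 1.5 d against 1 d and 2 d, quantile normalization 16 at 7 d, a median shift 7 at 14 d, no filter 0 and the strict filter 0 at 14 d, and the mean of probe sets 0 for 1.5 d against 1 d and 2 d. Unadjusted counts in the reported fit were 1761 at 7 d, 1870 at 14 d and 975 for that contrast. With an estimated correlation 0 of the 120 list calls were kept, and fry kept 90. With an array left out 90 of the 120 were kept in every case and 30 were lost in some, and with the strict filter 25 were weaker and 1 reversed. The median of the oncofetal list at 7 d, 0.165 in the reported fit, was -0.273 (camera adjusted p = 0.398) with the strict filter, which tests fewer of its genes. The stellate cell marker Loxl1 at 1 d went from 0.29 to -0.12 (adjusted p = 0.566) with the mean of its probe sets.

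Leaving out each array in turn gave 4885 to 6350 genes at 0.25 d, 3661 to 4685 at 0.5 d, 2249 to 2592 at 0.75 d, 1581 to 2278 at 1 d, 1889 to 2472 at 1.5 d, 2162 to 2841 at 2 d, 1893 to 2658 at 3 d, 87 to 361 at 4 d, 0 to 48 at 7 d, 0 to 23 at 14 d, 9047 to 9502 over all times and 0 to 42 for 1.5 d against 1 d and 2 d. The split of higher and lower genes turned without 0 d replicate 1 at 2 d (1233 and 1121) and 3 d (1023 and 1002), without 2 d replicate 1 at 2 d (1123 and 1039), without 3 d replicate 3 at 3 d (1225 and 1166) and without 0 d replicate 2 at 14 d (9 and 14). It also turned at 14 d without the arrays farthest on the first component (12 and 19) and with a joint adjustment (249 and 288). A time left with 2 arrays borrows its spread from the other groups. The lowest counts came without 1 d replicate 1 (1581), 3 d replicate 2 (1893), 0 d replicate 1 (87 at 4 d) and, at 7 d and 14 d, without 0 d replicate 1 (0 and 0).

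With the replicate number as a replicate block the counts were 6272, 4804, 3074, 2419, 2735, 3069, 2895, 388, 25 and 2 from 0.25 to 14 d, 2 for 1.5 d against 1 d and 2 d and 9358 over all times, all within 1.5 times of those without it, and the 120 list calls kept their side of the threshold. The labels do not say that a number is shared between times. Deviations of same-numbered arrays correlated at a mean of 0.0166 over 165 pairs (range -0.353 to 0.389, 33 pairs over 0.1). For differently numbered arrays of other times the mean was -0.00733. No broad effect shared by a number was seen, which does not settle whether same-numbered livers shared a day or batch.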

Other observations

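The tests of other splits of the samples were planned before the data were examined.

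Some genes of liver zonation also fell. At 0.5 d 7 of 14 periportal genes fell and 0 rose (8 and 0 adjusted over the list alone), with Hsd17b6 at -3.05 ± 0.42 and Etnppl at -2.42 ± 0.45 (camera adjusted p = 0.0242, and adjusted p = 0.623 with an estimated correlation). At the same time 6 of 17 pericentral genes fell and 0 rose (6 and 0 adjusted over the list alone), with Cyp1a2 at -2.96 ± 0.34, Rgn at -1.61 ± 0.18 and the vitamin C synthesis enzyme Gulo at -1.58 ± 0.16 (camera adjusted p = 0.00416, and adjusted p = 0.622 with an estimated correlation). The median difference of pericentral genes, -0.508, went to -0.770 without 0 d replicate 2 and -0.154 without 0.5 d replicate 3 (camera adjusted p = 0.0288). The R-spondin receptor Lgr5 (-1.57 ± 0.32) and the ubiquitin ligase Rnf43 (-2.10 ± 0.29) fell at 0.25 d. Of 17 hepatocyte transcription factors 3 rose and 5 fell at 0.25 d (3 and 5 adjusted over the list alone; camera adjusted p = 0.888, and adjusted p = 0.973 with an estimated correlation). Among them Cebpa was at -1.58 ± 0.23 at 0.25 d and -1.10 ± 0.23 at 2 d, while Cebpd was at 2.57 ± 0.40 at 0.25 d.

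Among cell type markers, erythroid genes fell in 3 of 7 cases at 2 d and rose in 0 (3 and 0 adjusted over the list alone), namely Car1 (-2.23 ± 0.19), Alas2 (-1.46 ± 0.18) and Klf1 (-1.33 ± 0.23; camera adjusted p = 0.0287, and adjusted p = 0.220 with an estimated correlation). The erythroid call was lost without 2 d replicate 2 (adjusted p = 0.0647), and the median difference of -0.165 went to -0.277 without 0 d replicate 2 and -0.0851 without 0 d replicate 3. Car1 (-1.72 ± 0.19), Alas2 (-1.41 ± 0.18) and Klf1 (-0.72 ± 0.23) were already lower at 0.25 d, where Ermap was higher (0.28 ± 0.11). At 1 d these 3 lower genes were at -2.33 ± 0.19, -1.52 ± 0.18 and -0.88 ± 0.23. Of 20 sinusoidal endothelium markers 1 rose at 0.25 d, the receptor Lyve1 (2.64 ± 0.44), and 6 fell, Kdr among them (-1.08 ± 0.16; 1 and 6 adjusted over the list alone; camera adjusted p = 0.904, and adjusted p = 0.982 with an estimated correlation). Hgf, the gene of hepatocyte growth factor, rose by 0.84 ± 0.16 and Igfbp3 fell by 2.04 at 2 d. Lymphocyte markers passed in 0 of 10 cases at each of the 10 times. Interferon response genes had a list mean of 8.74 on 0.25 d replicate 1 against 6.76 and 6.50 on the other 0.25 d arrays. Adipoq was 7.07 on 7 d replicate 3 and 5.86 on 2 d replicate 3, and Dpt, a fibroblast gene, was 9.10 on 0 d replicate 3 and 8.71 on 0.25 d replicate 2.

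Other splits of the same arrays were counted for each comparison. With 6 arrays there are 10 splits, too few for a share under 0.05. The real count of genes was reached by 1 of the 10 splits, the real one, from 0.25 to 7 d, and the highest other counts were 19, 49, 0, 0, 1, 112, 1, 2 and 0 against 6265, 4808, 3076, 2416, 2729, 3074, 2888, 390 and 25. At 14 d 4 of 10 splits gave at least the real count of 2, with 9 the highest other. Over the 11 times 1 of 100 regroupings, the real one, gave as many as 9470 genes, with 139 the highest other. That share is under 0.05, which argues against chance there. For 1.5 d against 1 d and 2 d 8 of 100 regroupings gave as many as 3 genes, so chance is not excluded, and the highest other was 1002. For lists called by camera, the splits with at least the real number were 3, 2, 8, 1, 2, 2, 1, 3, 10 and 9 of 10 from 0.25 to 14 d, with real numbers of 14, 16, 10, 15, 16, 14, 15, 11, 5 and 4 and highest others of 19, 18, 14, 13, 16, 14, 14, 18, 12 and 12. At 8 of the 10 times some other split thus gave at least as many lists as the real one. Every other split sets unequal mixes of the 2 times against each other and keeps a part of the real difference. Camera can still call that part, so these list numbers cannot tell whether the real list calls exceed chance.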
